A study of Mus musculus with 13 samples.

How the data were processed

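RNA was measured by mRNA sequencing in 13 mouse libraries. Per the labels' protocols, RNA was purified with a column kit, and libraries were built with the KAPA mRNA HyperPrep kit. Per the submitters' processing notes, Subread and featureCounts were used with mouse genome build mm10. The versions, settings and annotation release of these tools were not given in the sources used here.

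The deposited table held 1 value per gene and library for 21073 genes with Entrez identifiers, in log2 units that the authors had made as log2(RPKM + 1), where RPKM is the number of reads scaled to gene length and to the reads assigned in the library. The base of the logarithm was checked on the values. Read in base 2 and weighted by gene length, they summed to 1091000 to 1132000 per library, whereas base e gave 8260000 to 15760000. Genes without reads carried 0.0001, which was set to 0, and the highest value was 14.1. The values of the spinal cord APCs come from a column named for monocyte-derived cells of the DKI spinal cord, which was matched to the APC sample as the only sample and column left. Of the identifiers, 20857 matched the gene table used for symbols, and the other 216 kept the symbol in the deposited table.

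Read totals were estimated from the step between the values of genes with few reads, for which 1 read gives the smallest value above 0. The estimates ranged from 12600000 to 32000000 assigned reads per library. Among genes with 1 annotated transcript and up to 5 reads, 69.8% to 73.7% lay within 0.1 reads of a whole number at these totals, where values spread evenly would give 20%. These totals are needed for the counting intervals of the myeloid libraries, since each of those groups has 1 library. The intervals are exact binomial 95% intervals on the estimated reads (Clopper-Pearson) and cover counting error only, because PCR copies are not independent molecules and differences between animals are not measured.

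Gene lists, comparisons, filters and the rule for naming genes were fixed before the data were examined. The 10 Th17 libraries were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with eBayes and a mean-variance trend, and with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. It was tested where RPKM was at least 1 in at least 2 of the libraries compared (3 for the CCL17 comparison). DKI against WT, and DKI without CCL17 against DKI, were contrasts in a fit of all 10 Th17 libraries as group means, since a pair of libraries per group gives few residual degrees of freedom. The CCL17 comparison used its own 6 libraries. No protocol states that equal replicate numbers belong together. Residuals of libraries with the same number correlated at 0.77, 0.51 and 0.51 across genes in the CCL17 experiment. Replicates 2 and 3 also correlated across numbers (0.51 and 0.49), while replicate 1 stood apart from both (-0.61 to -0.64). The replicate number was therefore used as a block only as an alternative.

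Of 44 fixed lists, those with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry asks whether a list's own genes move one way. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method within a list. A further pair of lists, of up to 200 genes each, was drawn by a rule fixed with the others and held the genes with the smallest unadjusted p under 0.05 that were lower or higher in DKI than in WT cells, from a fit of those 4 libraries only. They were tested in the CCL17 comparison, which shares no library with them. Standard errors of list medians came from 1000 bootstrap draws over genes.

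The myeloid groups have no replicates and were compared without a test. Genes with RPKM of at least 5 in either library were counted where the log2 difference was 2 or more in size (4-fold). Each fixed list's median difference was placed among the medians of 10000 random lists matched on mean expression, and is given as a percentile.

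The genes named are, for each Th17 comparison, up to 12 genes per direction with the largest fold among those called whose groups did not overlap, 17 genes fixed for the question, and up to 4 members of each fixed list with the smallest p. The myeloid comparisons used the same rule with differences in place of p-values. Unnamed gene models and antigen receptor segments were left out. Some genes that the rule names are not reported here. Genes outside the rule are identified as such where they appear.

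The procedure was tested on simulated data with known changes, made from the observed means and spreads. Of genes shifted by 1 on the log2 scale, 82.8% were recovered for DKI against WT, 83% for the CCL17 comparison and 77.8% for DKI without CCL17 against DKI. Of genes shifted by 2, 95.8%, 97% and 95.9% were recovered. Among unchanged genes, 209 of 10823, 12 of 11007 and 58 of 11051 were called. For DKI against WT, these 209 outnumber the shifted genes recovered (82 at a shift of 1 and 92 at a shift of 2). The fit for that comparison thus called more unchanged genes than an adjusted p under 0.05 allows. All 3 lists that had been shifted were called in each comparison, and 0 of the other lists. The simulated noise was independent between genes and between libraries. The list counts therefore do not show how often camera at its preset correlation calls unchanged lists whose genes vary together. The shares of genes recovered likewise leave out the offset that replicate 1 shared between the CCL17 groups, so they may not hold for the real libraries.

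Alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter at RPKM 5, centring on the median gene, quantile normalization, TMM factors, eBayes without trend or with the robust option, other sets of libraries in the fit, the replicate block, and leaving out each library in turn. Trends with transcript length and GC content (GENCODE M21 transcripts) were removed by loess with a span of 0.5 where named. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not used here, so read quality, splicing and the knock-in alleles were not examined. The symbols of a list of mitochondrial genome transcripts did not match those of the table, which names these 10 genes otherwise, and the list was matched and tested alone after the other results were seen. WT myeloid libraries were not analysed here. The p-values of limma's gene tests and of fry measure only the spread between samples, which may be technical as well as biological. Camera at its preset correlation compares the statistics of a list's genes with those of the other genes, treated as nearly independent. Its p-values therefore do not show how far the fold of a list varies between libraries.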

Results

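Gene expression was measured by mRNA sequencing in 13 libraries from mice immunized with a myelin peptide in adjuvant. Such immunization is used to induce experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis, and raises autoreactive T cells. DKI mice carry knock-in changes in Stat5a (Entrez 20850) and Stat5b (Entrez 20851) that block STAT5 tetramers and leave dimers. Cells were taken on day 14 after immunization. The myeloid groups were sorted from DKI mice and hold 1 library each: bone marrow monocytes (32000000 estimated assigned reads), spinal cord monocytes (26800000) and monocyte-derived antigen-presenting cells (APCs) of the spinal cord (24600000). The Th17 groups came from spleen and lymph node cells that were expanded with the peptide under Th17 conditions for 3 days and then sorted for CD4+ T cells. They comprise WT (n = 2, 18200000 and 20400000 reads), DKI (n = 2, 18100000 and 20300000), DKI without CCL17 (n = 3, 14400000, 13800000 and 14000000) and DKI with CCL17 added to the culture (n = 3, 12600000, 15800000 and 14400000). CCL17 is a chemokine of monocyte-derived cells and a ligand of CCR4. All expression levels are log2(RPKM + 1).

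The first comparison asked how STAT5 tetramer-deficient monocytes that had entered the inflamed spinal cord differed from those still in the bone marrow. Inflammatory effector, chemokine and antigen presentation genes were far higher in the cord, and cell cycle, granule and classical monocyte genes were lower. Arg1 (Entrez 11846), the arginase of activated macrophages, was 1020-fold higher in RPKM (95% interval 851 to 1230) in the cord library. Il1b was 539-fold higher (465 to 629), and Nos2, the inducible nitric oxide synthase, was 2220-fold higher (1450 to 3590) over an estimated 21 reads in bone marrow monocytes. The invariant chain gene Cd74 was 99.7-fold higher (95.8 to 104). At the other end, the granule enzyme gene Mpo was 150-fold lower (121 to 189), and Top2a, which is needed for mitosis, was 42.9-fold lower (39.5 to 46.7).

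Among the fixed lists, 13 of 16 inflammatory monocyte cytokines and effectors were at least 4-fold higher in the cord library. Their median log2 difference was 5.71, and their percentile among 10000 random lists was 100. The list includes Acod1 (8.44), Ptgs2 (7.90) and Tnf (4.61). For chemokines the count was 14 of 16, with a median of 5.68, led by Ccl5 (9.17) and Cxcl16 (7.60). MHC class II and antigen presentation genes were 4-fold higher in 13 of 16 cases, with a median of 3.36, and H2-Eb1 was at 8.18 and H2-Ab1 at 5.73. Complement and Fc receptor genes had a median of 2.39 (9 of 15 at 4-fold), with C1qc at 8.35, and lipid handling genes of the phagolysosome had a median of 2.06 (11 of 19), with Gpnmb at 5.05 and Apoe at 4.16. Microglia markers moved with these lists (10 of 10 higher, 5 at 4-fold, median 2.48), with Olfml3 at 5.42 and Tmem119 at 3.23, and since microglia also express C1q, Apoe and class II genes, their share in the cord sort is not separated here from a change in the monocytes. All 25 interferon response genes (median 1.98) and all 22 glycolysis and hypoxia genes (median 1.78) were higher, among them Rsad2 (4.06), Isg15 (3.76), Vegfa (7.14) and the glucose transporter gene Slc2a1 (3.75). Of the IL-2 and STAT5 response genes, 9 of 11 were 4-fold higher and 1 was 4-fold lower, with a median of 3.21, and Cish (4.39) and Socs1 (4.34) were both among the higher ones. Heat shock and immediate early genes were higher in all 17 cases (8 at 4-fold, median 1.90), with Hspa1b at 5.14, Atf3 at 4.81 and Egr1 at 2.71. Cell isolation can raise these genes, and a difference in handling between the organs is not separated here from inflammation. Each of these lists stood at percentile 100.

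Cell cycle genes were 4-fold lower in 28 of 30 cases (median -3.58), including Kif11 (-5.02) and Ccna2 (-4.94). Neutrophil and granule genes were 4-fold lower in 12 of 14 cases (median -3.48), including Elane (-5.95) and Ctsg (-5.31). Whether the bone marrow sort held other cells that bring the transcripts of these lists was not examined. Classical monocyte genes had a median of -1.57, with 7 of 17 at least 4-fold lower. Ccr2, the receptor by which monocytes leave the marrow, was 5.04-fold lower (4.99 to 5.10), while Ly6c2 differed by only -0.56. All 3 lists were at percentile 0. Stat5a was 2.21-fold lower (2.03 to 2.41) and Stat5b 2.68-fold lower (2.55 to 2.83) in the cord library, and the GM-CSF receptor genes Csf2ra and Csf2rb differed by 0.34 and 0.54. Ribosomal protein genes (median -0.05, percentile 78.4) and oxidative phosphorylation genes (-0.41, percentile 19.5) lay near the median gene, which differed by -0.37.

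Of 8182 genes, 510 were at least 4-fold higher and 420 lower, so that 54.8% of the 930 were higher. With each library centred on its median gene, the counts were 602 higher and 319 lower (65.4% higher), and the median difference was -0.06. There are no replicates in any of the myeloid groups, so no p-value is given, the intervals cover counting error only, and a difference between the organs cannot be told from a difference between libraries.

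**Figure D1:**
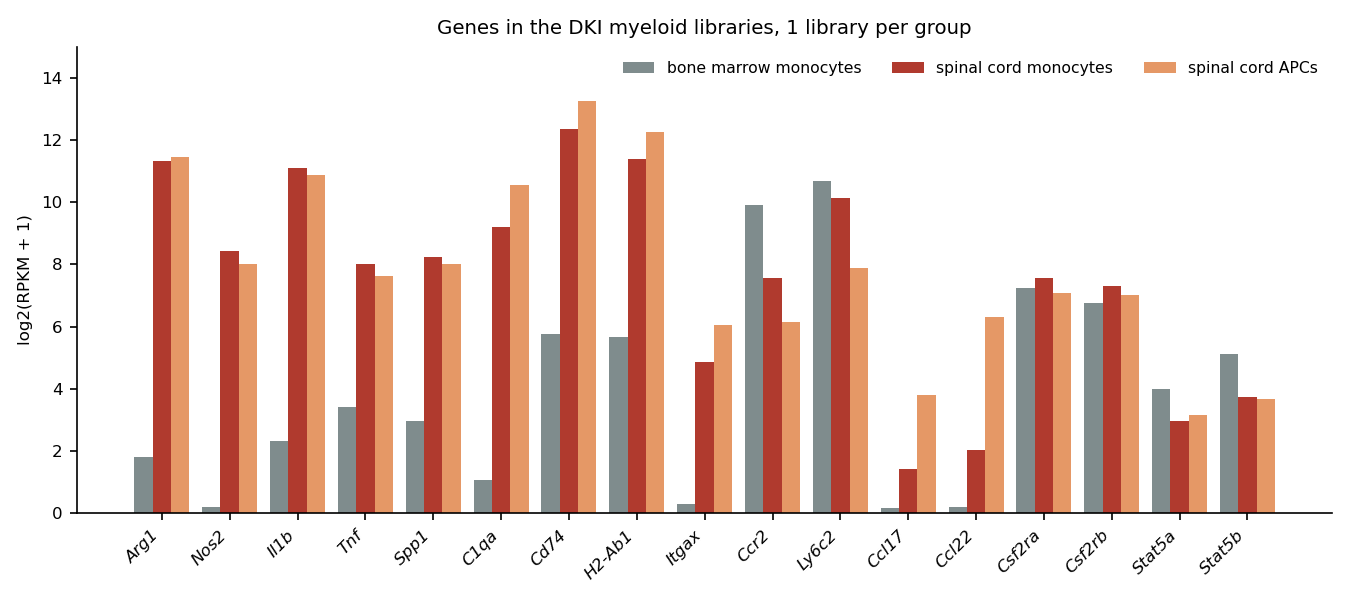
Expression (log2(RPKM + 1), bars from 0) of genes fixed for the myeloid comparisons, and of C1qa, in DKI bone marrow monocytes, spinal cord monocytes and spinal cord APCs, with 1 library per bar and no error bars. Arg1 stands at 1.81 in the bone marrow bar and at 11.33 and 11.46 in the spinal cord bars, and Ccl22 stands at 0.21, 2.03 and 6.31.

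The next comparison set spinal cord APCs against spinal cord monocytes, which the labels name as their origin, and includes the gene of the chemokine that the study is about. Ccl22 and Ccl17, neighbouring genes for the ligands of CCR4, were both higher in the APC library. Ccl22 was 25.5-fold higher (22.0 to 29.7). Ccl17 (Entrez 20295) was 7.72-fold higher (4.97 to 12.5), from an estimated 23 reads in cord monocytes and 162 in APCs. Its levels were 0.16, 1.41 and 3.79 in bone marrow monocytes, cord monocytes and APCs, and the bone marrow value stands for about 2 reads. Ccr7, which guides dendritic cells to lymph nodes, was 20.7-fold higher (17.2 to 25.2) in APCs. Vcan was 40.0-fold lower (32.9 to 49.1) and Ly6c2, a surface marker of classical monocytes, was 4.77-fold lower (4.62 to 4.91).

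Dendritic cell markers had the largest list median, 1.90 at percentile 100, with 3 of 6 members 4-fold higher (Ccr7 at 3.86, Fscn1 at 2.85 and Cacnb3 at 2.34). MHC class II and antigen presentation genes were higher in 12 of 16 cases, with a median of 0.55, and lipid handling genes had a median of 0.53. H2-DMb2 differed by 1.92, Cd74 by 0.89, H2-Ab1 by 0.86 and Itgax by 1.19. All 11 microglia markers were higher (median 1.48), with Tmem119 at 1.66 and Sall1 at 1.64. As microglia also express class II genes and Apoe, their share in the APC sort is not separated here from a difference between monocytes and APCs. The neutrophil and granule list had a median of 0.69, with Ltf at 2.22. Classical monocyte genes had a median of -0.86, with 4 of 17 at least 4-fold lower, among them Vcan (-3.36) and Plac8 (-2.10), and Ccr2 differed by -1.41. The interferon response list had a median of -0.79, and 24 of 25 members were lower, including Isg15 (-1.39) and Ifit1 (-1.26). Inflammatory monocyte cytokines and effectors had a median of -0.34 at percentile 0.2. Arg1 (0.14), Il1b (-0.22) and Nos2 (-0.42) were close between the libraries, as were Stat5a (0.19) and Stat5b (-0.07). IL-2 and STAT5 response genes had a median of -0.41 at percentile 0. The list of the GM-CSF receptor and its response genes, which holds Ccl17 and Ccl22, had a median of -0.04 at percentile 28.9, with 3 of 13 genes 4-fold higher.

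In total, 18 of 7499 genes were at least 4-fold higher in APCs and 6 were lower (0.32% together), and the median gene differed by 0.03. Pearson's r across genes, which are not independent replicates, was 0.992 between the spinal cord libraries and 0.916 and 0.911 between the bone marrow library and each of them.

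DKI and WT Th17 cells were compared to ask what loss of STAT5 tetramers does to the T cells themselves. No single gene passed the test, but interferon response, naive and memory T cell, follicular helper (Tfh) and myeloid marker genes were lower as lists in DKI cells, and cholesterol synthesis, glycolysis and cell cycle genes were higher. These are calls of camera at its preset correlation, and the smallest adjusted p was 0.88 with an estimated correlation. The interferon response list had the largest median log2 fold, -1.42 over 25 genes (n = 2 and 2). Without WT replicate 1, the interferon (-0.35), cholesterol synthesis (0.04), glycolysis (0.12) and cell cycle (-0.07) calls ended, as did the Tfh (-0.39) and cell cycle (-0.13) calls without DKI replicate 2. Csf2, the gene for the cytokine GM-CSF, was 5.87 ± 0.33 in WT and 6.78 ± 0.68 in DKI cells (SD, n = 2 each), a log2 fold of 0.91 (SE 0.28, adjusted p 0.181). Its libraries stood at 6.10 and 5.63 in WT and at 7.26 and 6.30 in DKI cells, so the size of the fold depends on the DKI library kept. Il17a was 8.67 in both WT libraries and 10.38 and 7.57 in the DKI libraries, so that its fold of 0.30 (SE 0.81, adjusted p 0.859) lay within the spread of the DKI pair.

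Stat5a (-0.05, SE 0.15, adjusted p 0.871), Stat5b (-0.30, SE 0.10, adjusted p 0.212) and the CCL17 receptor gene Ccr4 (0.28, SE 0.13, adjusted p 0.317) did not pass the test either. The smallest adjusted p was 0.0659, shared by 7 genes. Of the genes named here, the smallest adjusted p was 0.093, for Casp1 (0.61, SE 0.10), which encodes the protease that activates IL-1β, for Bcl6 (-0.77, SE 0.13), the regulator of Tfh cells, and for the acute phase gene Saa3 (-2.26, SE 0.38). Tbx21, which encodes T-bet, had a fold of 0.63 (SE 0.24) and Il22 of -0.77 (SE 0.33). The Th17 program list (median 0.17, adjusted p 0.491), the pathogenic Th17 list (-0.08, adjusted p 0.712) and the IL-2 and STAT5 response list (-0.02, adjusted p 0.865) were not called. By fry's mixed test, which counts changes in either direction, the pathogenic Th17 list (adjusted p 0.0063) and the Tfh list (adjusted p 0.046) passed.

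**Figure D2:**
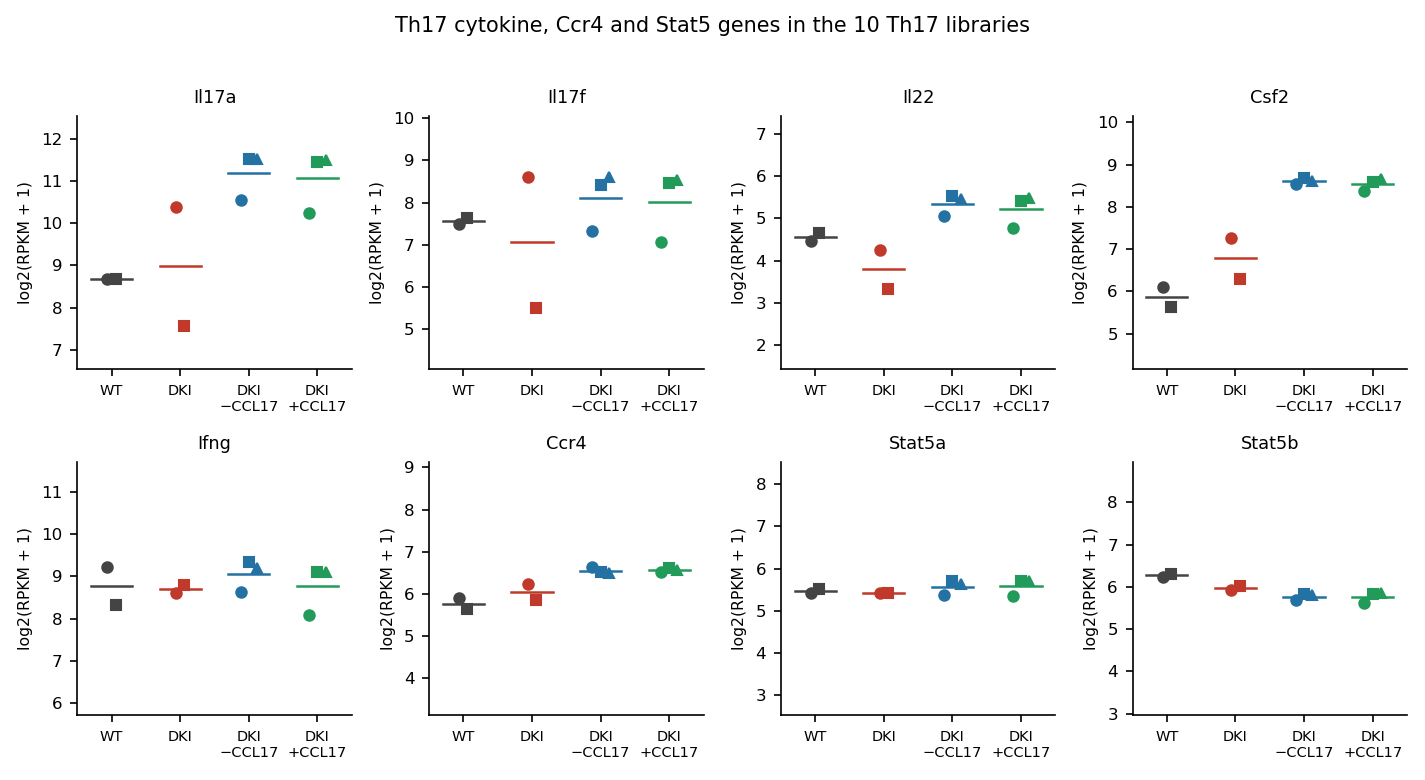
Expression (log2(RPKM + 1)) of 8 genes in the 10 Th17 libraries by group (WT, DKI, DKI without CCL17, DKI with CCL17). Points are libraries, with the symbol giving the replicate number (circle 1, square 2, triangle 3), and lines are group means. Il17a differs more between the DKI libraries (10.38 and 7.57) than between the groups with and without CCL17.

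Camera called 13 of 37 lists, 8 lower and 5 higher in DKI cells, and 0 at an adjusted p of 0.88 with an estimated correlation (fry called 0, smallest adjusted p 0.35). Interferon response genes had an adjusted p of 1.09e-07, and their library medians were 7.29 and 5.25 in WT and 4.20 and 5.43 in DKI. The members with the smallest p include Oas3 (-1.28), Ifit1 (-1.87) and Ddx58 (-0.97). None of the 25 was called, over all genes or adjusted over the list alone. Naive and memory T cell genes had a median of -0.57 (adjusted p 1.46e-05). None of the 12 passed over all genes, and 4 were lower when adjusted over the list alone, with Tcf7 at -0.82, Bach2 at -0.72 and Lef1 at -0.56. The Tfh list had a median of -0.35 (adjusted p 0.00146), with 4 of 11 lower when adjusted over the list alone, Bcl6 and Tox (-0.76) among the members. Myeloid markers were also lower (median -0.96, adjusted p 2.19e-06, 4 of 10 when adjusted over the list alone), with library medians of 2.53 and 2.03 in WT and 1.15 and 1.80 in DKI. Lyz2 had a fold of -1.49 and Tyrobp of -1.35. The complement (median -0.89, adjusted p 0.000204), neutrophil (-0.82, 0.0269) and lipid handling (-0.28, 0.0297) lists, whose members myeloid cells also express, were lower too, as was the MHC class I pathway (-0.25, 0.0175). Adjusted over the list alone, 3 of 8, 1 of 6, 2 of 15 and 0 of 11 genes of these lists were lower, and over all genes none was. Cholesterol synthesis had a median of 0.57 (adjusted p 9.6e-06), with Cyp51 at 0.74 and Msmo1 at 0.66, glycolysis and hypoxia of 0.38 (0.000299), oxidative phosphorylation of 0.18 (0.000633), cell cycle of 0.36 (0.00693) and ribosomal proteins of 0.14 (0.0296). None of the genes in these 5 lists passed, adjusted over the list alone. Across all genes, folds fell with transcript length in this comparison (Spearman's rho -0.24), with a log2 fold of 0.108 among the shortest genes. Lists were tested again with this trend removed, but only the total number called was kept. Whether the trend adds to the 5 higher calls is therefore not shown.

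Single libraries carried much of this. Without WT replicate 1, the interferon (-0.35), cholesterol (0.04), glycolysis (0.12), oxidative phosphorylation (0.04), cell cycle (-0.07), MHC class I (-0.08), ribosomal (-0.02) and lipid handling (-0.28) calls ended, and the myeloid and complement medians were -0.60 and -0.54. Without DKI replicate 2, the oxidative phosphorylation (0.10), Tfh (-0.39), cell cycle (-0.13), neutrophil (-0.95) and ribosomal (0.14) calls ended, and the naive and memory list was at -1.04 and MHC class I at -0.40. Without DKI replicate 1, MHC class I (-0.04), ribosomal (0.16) and lipid handling (-0.22) calls ended, and the interferon list was at -0.82, the naive and memory list at -0.17, the complement list at -0.59 and the cell cycle list at 0.84. Without WT replicate 2, interferon stood at -2.37, cholesterol at 1.09, cell cycle at 0.77, Tfh at -0.64, oxidative phosphorylation at 0.34, ribosomal proteins at 0.31 and neutrophil genes at -0.54. The myeloid, complement and naive and memory calls were made in all 4 of these fits.

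Over all 11078 genes, limma called 0. At an unadjusted p under 0.05 there were 914 higher and 965 lower genes, where chance gives 554, and the fit of these 4 libraries alone gave 645 and called 0 (smallest adjusted p 0.64). The groups did not overlap in 4425 genes, 39.9% where chance gives 33.3%. Leaving out 1 library gave 0 higher and 1 lower gene without WT replicate 1, 70 and 75 without WT replicate 2, 4 and 7 without DKI replicate 1, and 277 and 282 without DKI replicate 2, and quantile normalization gave 1 and 6.

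**Figure D3:**
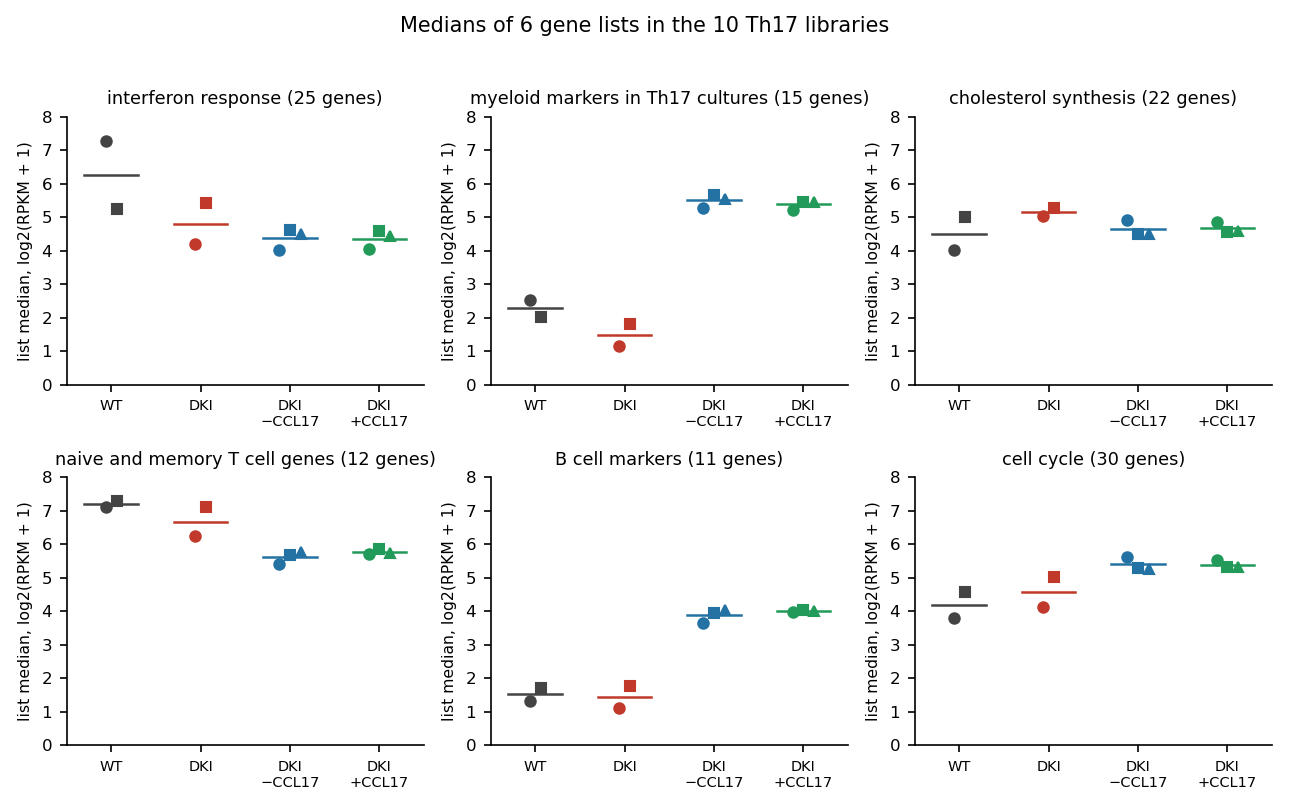
Median expression (log2(RPKM + 1)) over the genes of 6 fixed lists in each of the 10 Th17 libraries. Points are libraries, with the symbol giving the replicate number (circle 1, square 2, triangle 3), and lines are group means. WT replicate 1 stands at 7.29 for interferon response genes, and myeloid markers are at 1.15 to 2.53 in the WT and DKI libraries but at 5.23 to 5.66 in the 6 libraries of the CCL17 experiment.

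The CCL17 comparison asked what the chemokine does to DKI Th17 cells in culture. No gene passed the test, and the group means of the Th17 cytokine genes were close with and without it. Il17a was 11.20 ± 0.55 without and 11.07 ± 0.72 with CCL17 (SD, n = 3 each), a log2 fold of -0.14 (SE 0.42). Csf2 was 8.62 ± 0.08 and 8.54 ± 0.15, a fold of -0.08 (SE 0.10), and Ccr4 was 6.55 ± 0.07 and 6.58 ± 0.05, a fold of 0.03 (SE 0.06). As lists, complement, lipid handling and other macrophage genes were lower with CCL17, by -0.28 for complement and Fc receptors, and naive and memory T cell and B cell genes were higher (smallest adjusted p 0.87 with an estimated correlation).

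Il17f (-0.09, SE 0.49), Il22 (-0.13, SE 0.22), Ifng (-0.30, SE 0.32), Stat5a (0.02, SE 0.13) and Stat5b (0.01, SE 0.08) all had an adjusted p of 0.999. These SEs include the offset of replicate 1. In replicates 1, 2 and 3, Ifng was 8.64, 9.35 and 9.21 without and 8.09, 9.10 and 9.11 with CCL17. Il17a was 10.56, 11.52 and 11.52 without and 10.24, 11.46 and 11.50 with it. Both were thus lower in each same-number pair, while Il17f, Il22 and Csf2 went both ways. None of these genes passed with the replicate block. The Th17 program list had a median of 0.00, the pathogenic Th17 list of -0.13 (adjusted p 0.118) and the IL-2 and STAT5 response list of -0.06 (adjusted p 0.163). With the replicate block, camera called the pathogenic Th17 list lower (adjusted p 0.000376, and 0.531 with an estimated correlation), with medians of -0.10, -0.12 and -0.01 in the same-number pairs. The block also gave lower calls for the GM-CSF (median -0.10, adjusted p 0.00141), T cell marker (-0.06, 0.00412), cytotoxic (-0.12, 0.00522), glycolysis and hypoxia (-0.05, 0.0200), T cell cytokine (-0.09, 0.0250) and IL-2 and STAT5 response (-0.06, 0.0260) lists, all at an adjusted p of 0.531 or more with an estimated correlation. Camera called 11 of 39 lists, 9 lower and 2 higher with CCL17, and 0 at an adjusted p of 0.87 with an estimated correlation (fry called 0, smallest adjusted p 0.66). Complement and Fc receptor genes had an adjusted p of 1.11e-07. C1qc, a subunit of the complement component C1q, was 5.12 ± 0.02 without and 4.62 ± 0.07 with CCL17 (SD, n = 3 each), a fold of -0.50 (SE 0.06) at an adjusted p of 0.976. C1qa was at -0.40 (SE 0.08) and C1qb at -0.32 (SE 0.09). Of the 15 genes, 0 passed over all genes and 2 were lower adjusted over the list alone. Lipid handling genes had a median of -0.26 (adjusted p 4.67e-06, 0 of 20 adjusted over the list alone), with Trem2 at -0.68 (SE 0.21) and Ctsl at -0.43 (SE 0.14). Myeloid markers moved with these lists, with a median of -0.28 (adjusted p 2.23e-05, 1 of 15 adjusted over the list alone) and medians of -0.19, -0.32 and -0.37 in the 3 same-number pairs. Chemokines (median -0.20, adjusted p 0.00169), alternative activation genes (-0.23, 0.0143) and inflammatory monocyte genes (-0.14, 0.0423) were lower too, with Mmp12 at -0.45, Ccl6 at -0.35 and Ccl9 at -0.32.

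Among lists of T cell and general functions, naive and memory T cell genes had a median of 0.08 (adjusted p 0.00548), with Bach2 at 0.26 and Lef1 at 0.08. Oxidative phosphorylation (median -0.09, adjusted p 6.54e-05), ribosomal proteins (-0.07, 0.0153) and the MHC class I pathway (-0.09, 0.0173) were lower. Across all genes, folds rose with transcript length in this comparison (Spearman's rho 0.38). The log2 fold was -0.058 among the shortest genes and 0.05 among the longest. In DKI against WT cells folds fell with length (rho -0.24), and there oxidative phosphorylation and ribosomal proteins were called higher. Whether the length trend gives the calls of the CCL17 comparison was not tested. B cell markers had a median of 0.13 (adjusted p 0.0143), with Ms4a1 at 0.17 and Ighd at 0.19, and their medians in the pairs were 0.34, 0.07 and -0.02. None of the genes in these 5 lists or the 3 before them passed in this fit, adjusted over the list alone. The replicate block changed these counts: adjusted over the list alone, 15 of 15 myeloid, 14 of 15 complement, 12 of 20 lipid handling, 11 of 18 chemokine, 5 of 17 inflammatory monocyte and 4 of 10 alternative activation genes were lower. So were 4 of 16 pathogenic Th17, 4 of 14 GM-CSF list and 3 of 11 MHC class I genes, with 1 MHC class I gene and 1 of 12 naive and memory genes higher. None of these list members passed over all genes with the block, and every list had an adjusted p of 0.531 or more with an estimated correlation. The complement, lipid handling and alternative activation calls were made whichever of the 6 libraries was left out. With replicate 1 of the CCL17 cultures left out, the myeloid (-0.08), chemokine (-0.03), MHC class I (-0.06) and inflammatory (0.10) calls ended, complement was at -0.15, lipid handling at -0.13, oxidative phosphorylation at -0.14 and ribosomal proteins at -0.13. With replicate 1 of the cultures lacking CCL17 left out, the oxidative phosphorylation (-0.03), naive and memory (0.03), B cell (0.00) and ribosomal (-0.04) calls ended, and the complement, lipid handling, myeloid, chemokine and inflammatory medians were -0.45, -0.48, -0.47, -0.46 and -0.44. With replicate 2 or 3 of the latter left out, the MHC class I (-0.07 and -0.08) and inflammatory (-0.02 and -0.03) calls ended, the myeloid medians were -0.17 and -0.14, the lipid handling medians were -0.16 and -0.17, the B cell medians were 0.19 and 0.26, and the chemokine list was at -0.11, where its call ended, and -0.13. With replicate 2 of the CCL17 cultures left out, the oxidative phosphorylation (-0.04) and ribosomal (-0.02) calls ended, alternative activation was at -0.08 and the inflammatory list at -0.27. With replicate 3 of them left out, the B cell (0.11) and ribosomal (-0.04) calls ended, chemokines were at -0.34 and the inflammatory list at -0.26.

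**Figure D4:**
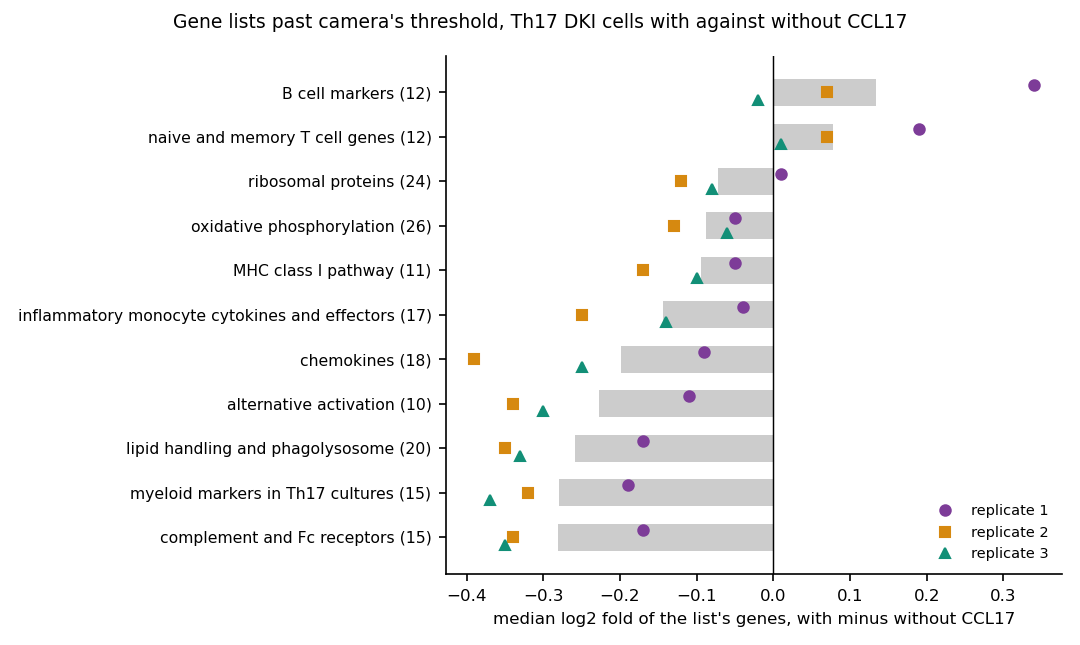
Median log2 fold (with minus without CCL17) of the genes of each of the 11 lists called in the CCL17 comparison. Bars are medians of the genes' group folds, with the number of genes tested in brackets, and symbols are the same lists in each same-number pair of libraries. Complement and Fc receptor genes lie at -0.17, -0.34 and -0.35 in the pairs.

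Over all 11297 genes, limma called 0, with a smallest adjusted p of 0.976. At an unadjusted p under 0.05 there were 239 higher and 172 lower genes, where chance gives 565, and 1524 with the replicate block. The groups did not overlap in 1072 genes, 9.5% where chance gives 10% if all 6 libraries are alike in structure. Replicate 1 stood apart in both groups, so this share does not show an absence of change. With the replicate number as a block, 2 genes passed, the T cell receptor segments Traj20 (1.29) and Traj31 (1.05), each at an adjusted p of 0.025. With a term for replicate 1 against the others, 7 genes passed, all lower with CCL17: C1qc (-0.50), Trem2 (-0.68), Spp1 (-0.50), Ctsl (-0.43), Ccl2 (-0.40), Plau (-0.45) and Gpnmb (-0.38). With replicates 2 and 3 alone, 85 genes were higher and 123 lower. Among genes with 20 to 200 reads, these replicates differed by 1.78 (without CCL17) and 1.67 (with CCL17) times the variance of counting error. Against replicate 1 of the same group the ratios were 6.09 to 6.62. No label says whether replicates 2 and 3 are separate cultures, so their calls may rest on a spread that is mostly technical. The genes of the block and of the replicate term were named after their values were seen.

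Whether CCL17 moves genes that stood apart between the WT and DKI libraries was tested on lists drawn from those 4 libraries, which the CCL17 comparison does not use. None of the listed genes passed an adjusted test of genotype (limma, smallest adjusted p 0.64, and 645 genes at an unadjusted p under 0.05 where chance gives 554), so many of them may be chance picks. Genes lower in DKI than in WT cells were higher with CCL17, by a median log2 fold of 0.11 (bootstrap SE 0.013 over 190 genes), and 152 of them (80%) were higher, against 45.3% of the other genes. This list holds Bcl6, Tox and Cxcr5 of the Tfh list and Apoe, Itgam and Tyrobp, which macrophages express. Its 14 members of the fixed lists went both ways (6 higher and 8 lower, median -0.03), as did its T cell receptor and immunoglobulin segments (16 higher and 12 lower, median 0.07), while 130 of the other 148 tested genes were higher (median 0.12). Genes higher in DKI than in WT cells were lower with CCL17, by a median of -0.043 (SE 0.007 over 197 genes). Of them, 58 (29.4%) were higher, against 46.1% of the other genes (camera p 0.0556 with an estimated correlation). That list holds Casp1, Tbx21 and Il12rb2, and with CCL17 Casp1 was at -0.15 (SE 0.09) and Tbx21 at 0.01 (SE 0.22). Its 10 members of the fixed lists went both ways (3 higher and 7 lower, median -0.04).

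For the genes lower in DKI, camera gave a p of 5.34e-18, and 0.0429 with an estimated correlation (fry 0.0555). The medians in the 3 same-number pairs were 0.096, 0.166 and 0.089, and 0.106 with the replicate block. The list depends on the libraries it was drawn from. Lists drawn in the same way from the other splits of the WT and DKI libraries, a test chosen after the data were seen, had CCL17 medians of -0.005 and -0.021 (split by replicate number, which gave 1186 genes at an unadjusted p under 0.05) and of -0.084 and -0.045 (38 and 21 genes), with camera p from 0.0583 to 0.767. Its median was 0.000 (camera p 0.137) without WT replicate 2, 0.067 without WT replicate 1, 0.059 without DKI replicate 2 and 0.072 without replicate 1 of the cultures lacking CCL17. Its genes were long, with a median transcript length of 5089 nt against 3135 nt for all genes, and with the length trend of each library removed the median was 0.048. For the genes higher in DKI, camera gave a p of 0.000103, and 0.0556 with an estimated correlation (fry 0.0482), with pair medians of -0.025, -0.061 and -0.039. Without DKI replicate 2 the median was -0.030 and the call ended, and it was -0.083 without WT replicate 1, -0.027 without DKI replicate 1 and -0.021 with the length trend removed.

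**Figure D5:**
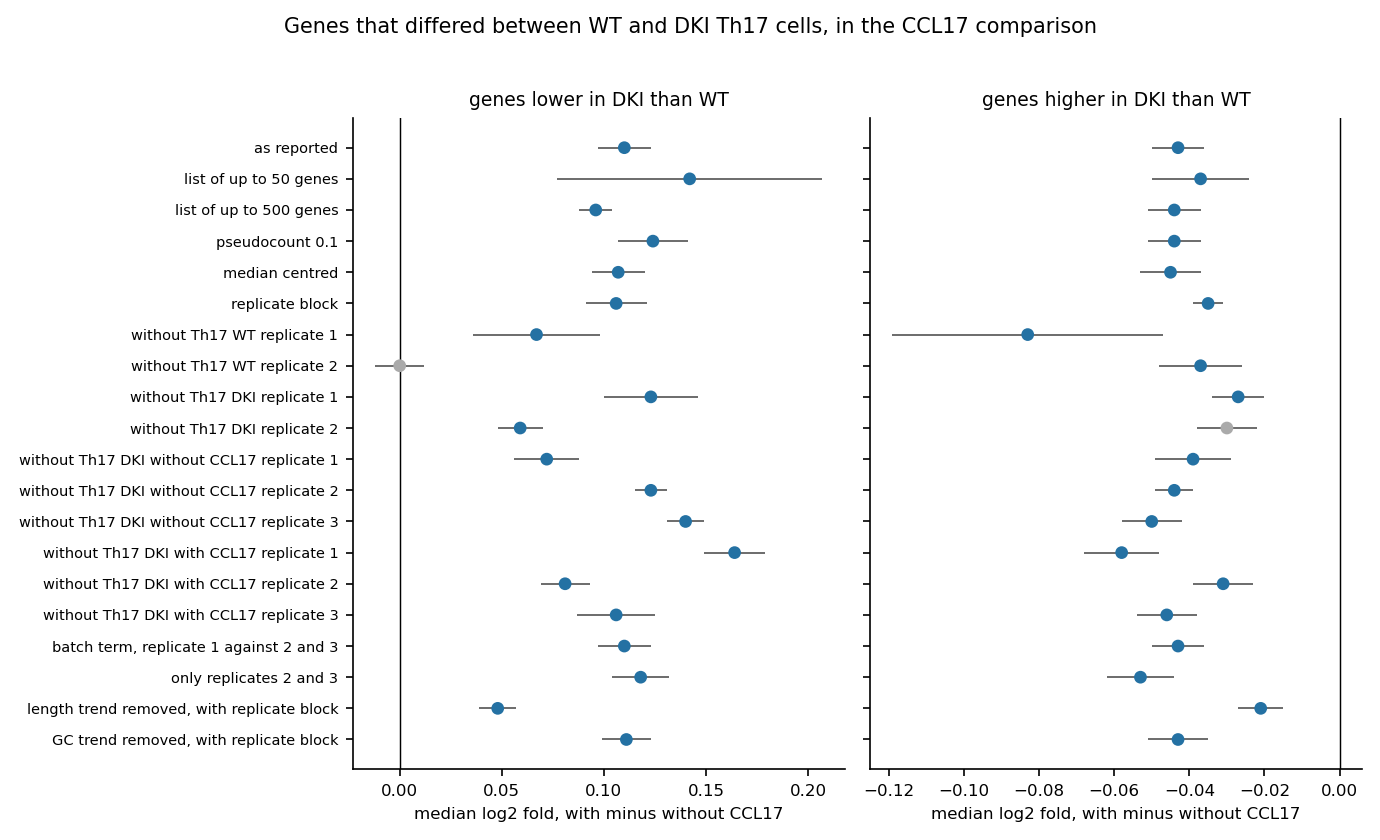
Median log2 fold (with minus without CCL17) of the genes lower and higher in DKI than in WT Th17 cells, as reported and under each alternative setting. Points are medians, lines are plus or minus 1 bootstrap SE over genes, and grey points are settings in which camera's p was not under the threshold of 0.05. The reported medians are 0.11 and -0.043, and the grey points are at 0.000 without WT replicate 2 and -0.030 without DKI replicate 2.

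DKI Th17 cells without added CCL17 form a pair of groups, one beside WT cells and one in the CCL17 experiment, with labels that give the same genotype and no added CCL17. Their comparison measures how far these sets of cultures differ. The libraries without CCL17 carried far more RNA of macrophages, neutrophils and B cells. Lyz2, the lysozyme gene of myeloid cells, was 2.78 ± 0.97 in DKI cells (n = 2) and 8.69 ± 0.23 in DKI cells without CCL17 (SD, n = 3), a log2 fold of 5.91 (SE 0.38, adjusted p 4.6e-05). Csf2 rose from 6.78 ± 0.68 to 8.62 ± 0.08, a fold of 1.84 (SE 0.26, adjusted p 0.00142), and Cd27, a costimulatory receptor of naive and memory T cells, fell by 1.87 (SE 0.16, adjusted p 0.000173).

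All 15 myeloid markers rose (median 4.39), as did all 15 complement and Fc receptor genes (3.86), 19 of 20 lipid handling genes (1.88), 14 of 19 chemokines (2.94), 14 of 17 inflammatory monocyte genes (2.45), 12 of 14 neutrophil genes (2.13), 9 of 10 alternative activation genes (2.78) and all 11 B cell markers (2.06), each count being the same or 1 lower than that adjusted over the list alone. The largest folds were those of the chemokine genes Ccl2 (6.91, SE 0.74) and Ccl7 (6.88), the collagenase gene Mmp13 (6.81) and Pf4 (6.80). S100a8 (5.90), S100a9 (5.78), Mrc1 (4.97), Itgam (3.73), Ms4a1 (2.69), Cd79b (2.58), H2-Ab1 (2.17) and Cd74 (2.00) rose too, along with 10 of 16 MHC class II genes (median 1.06). Of the classical monocyte genes (median 1.48), 9 of 16 rose and 2 fell, or 10 and 3 adjusted over the list alone. Camera called these 10 lists, but none with an estimated correlation (adjusted p 0.0513 to 0.331).

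Among lists of T cell functions, 8 of 16 pathogenic Th17 genes rose (median 0.62), including Csf2, Il22, Cxcl3 (3.58) and Lgals3 (2.81). Lgals3 stood at 1030 RPKM in cord monocytes, so macrophage RNA may raise this list in part. Members also rose among the lists of T cell cytokines and of the cell cycle, with 7 of 22 cytokine genes higher and 1 lower (median 0.39) and 8 of 30 cell cycle genes higher (median 0.39), such as Ccnb1 (1.74). Il17a (2.23, SE 0.74, adjusted p 0.0481), Il22 (1.56), Il13 (1.90) and Ccr4 (0.50) were higher. Il17a was 10.38 and 7.57 in the DKI libraries and 10.56, 11.52 and 11.52 in those without CCL17, so the size of its fold depends on the DKI library kept. Naive and memory T cell genes fell in 10 of 12 cases (median -1.18, adjusted p 3.39e-05), or 11 of 12 adjusted over the list alone, with Igfbp4 at -1.69, Tcf7 at -1.43 and Bach2 at -1.06. Foxp3 (-1.47) and Lrrc32 (-1.20) of regulatory T cells and Cxcr3 (-1.15) fell as well. The list of T cell markers fell by less (median -0.31, 7 of 12 lower and 1 higher), with Trac at -0.46 and Lck at -0.55. In the GM-CSF list, 6 of 14 genes rose and 2 fell (median 0.66), with Gpnmb (5.57), Ccl24 (3.39) and Csf2rb (3.26), which macrophages express, at its head. Camera called the naive and memory, T cell marker, pathogenic Th17, cytokine, cell cycle and GM-CSF lists, but none with an estimated correlation (adjusted p 0.252 to 0.761). Adjusted over the list alone, 9 cytokine genes rose, 1 pathogenic Th17 gene fell, and the other counts of these lists were as given. Stat5a (0.14, adjusted p 0.451) and Stat5b (-0.21, adjusted p 0.114) did not pass.

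In this comparison, limma called 1777 higher and 2046 lower of 11507 genes (46.5% of the called genes higher), with a smallest adjusted p of 1.27e-07, and the groups did not overlap in 6399 genes, 55.6% where chance gives 20%. TMM factors gave 2353 higher and 1558 lower (60.2% higher), quantile normalization 1448 and 2580 (35.9% higher), and the replicate block 578 and 255, and the counts were 1157 and 1538 without replicate 2 and 1109 and 1404 without replicate 3 of the cultures lacking CCL17. Restricted to the 5 libraries compared, the fit called 1199 and 1224. Camera called 16 of 40 lists, 14 higher and 2 lower, and fry called 19.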

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

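The removal of length and GC trends, the term for replicate 1 and the use of replicates 2 and 3 alone were chosen after the data were seen, as was, for the fixed lists only, a fit of the WT and DKI libraries alone. For DKI against WT Th17 cells, the 0 genes called became 1 higher and 6 lower with quantile normalization and 1 higher with the length trend removed, and from 0 to 277 higher and 1 to 282 lower when 1 library was left out. The 13 lists became 0 with camera at an estimated correlation, 0 with fry and 7 to 16 when 1 library was left out. For CCL17, the 0 genes became 2 higher with the replicate block, 7 lower with the term for replicate 1, and 85 higher and 123 lower with replicates 2 and 3 alone. The 11 lists became 0 with an estimated correlation, 0 with fry, 18 with the block, 18 with the term for replicate 1 and 19 with replicates 2 and 3 alone, and 9 to 13 when 1 library was left out. That count of fry is for the reported fit. For the myeloid, lipid handling and complement lists, fry's adjusted p was 0.185, 0.188 and 0.185 with the block. It was 0.0488 for each with the term for replicate 1, and 0.0191, 0.0191 and 0.0330 with replicates 2 and 3 alone. With an estimated correlation, camera gave these 3 lists an adjusted p of 0.2165 or more in those fits. For DKI without CCL17 against DKI, the 2046 lower genes became 1224 with only the libraries compared, the block gave 578 higher and 255 lower, where replicate 3 has no partner among the DKI libraries, and leaving out 1 library gave 1109 to 1824 higher and 1404 to 1838 lower. The median of the genes lower in DKI ranged from 0.000 to 0.164 in the CCL17 comparison when 1 library was left out. That of the genes higher in DKI ranged from -0.083 to -0.027, and its call ended with an estimated correlation, at the same median of -0.043. The cause of these changes was not tested, except that fry asks a different question of the same values and that fewer libraries give a different estimate of the spread. Camera with an estimated correlation asks the same question as at the preset 0.01, but allows for genes of a list that vary together. The estimates were 0.874 for interferon response and 0.789 for cholesterol synthesis genes in DKI against WT. In the CCL17 comparison they were 0.819 for myeloid markers and -0.067 for alternative activation genes. The counts of genes 4-fold apart in the myeloid comparisons stayed within 1.5 times the reported ones under every pseudocount, filter and scaling tried (535 to 602 higher and 319 to 498 lower for the cord monocytes, 12 to 24 and 6 to 9 for the APCs). Of 1926 values of named genes under the alternatives, 1769 kept their side of the threshold or moved less than the counting interval (26 changed sign without being called in either fit), 42 passed the threshold newly, 18 no longer passed it, 97 moved beyond the counting interval in the myeloid comparisons, and 0 that were called reversed. Depth limits Ccl17, since its bone marrow value rests on about 2 reads.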

Other observations

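Tests chosen after the result was seen were those on the loss of all non-T cells alike, on the normalization, on naive and memory T cell genes and on splits of the genes called. So were the alternatives with length or GC trends removed, with the term for replicate 1 and with replicates 2 and 3 alone. The same holds, for the fixed lists only, for the fit of the WT and DKI libraries alone. The tests of mitochondrial transcripts and of lists from other splits of the WT and DKI libraries were also chosen then.

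Markers of other cell types were also detected in the spinal cord sorts. Microglia markers had a median of 0.68 in bone marrow monocytes, 4.58 in cord monocytes and 5.55 in cord APCs. T cell markers had medians of 0, 1.91 and 2.13 in the same order, against 8.29 over the Th17 libraries, with Trac at 0.05, 2.83 and 2.87. Neural and glial markers had medians of 0, 1.13 and 1.26, erythroid markers of 0.08, 1.31 and 1.21, and endothelial and stromal markers of 0.01, 0.71 and 0.86. B cell markers stayed at 0.06, 0.20 and 0.42. Some microglia markers, such as Cst3, are also expressed by macrophages, so the microglia values do not measure a share of microglia.

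Within the CCL17 experiment, replicate 1 of both groups stood apart from replicates 2 and 3. Il17a was 10.56 and 10.24 in replicate 1 without and with CCL17, and 11.46 to 11.52 in the other 4 libraries. Neutrophil and granule genes had medians of 4.76 and 5.05 in replicate 1 and 3.81 to 3.90 in the others. Cholesterol synthesis genes were at 4.93 and 4.86 against 4.49 to 4.58, and endothelial and stromal markers at 3.20 and 3.14 against 4.12 to 4.37. These values were not tested as a comparison, since no label separates the replicates.

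Genes lower in DKI than in WT Th17 cells were higher with CCL17 by a median of 0.11, and an effect of CCL17 stays open, although no listed gene passed an adjusted test of genotype or was shown to depend on STAT5 tetramers. A GC trend between libraries is not the whole cause, since the median was 0.111 (SE 0.012) in the blocked fit with that trend removed. Myeloid RNA in the list worked against the rise, since myeloid markers were lower with CCL17 (median -0.28), and the median was 0.127 (SE 0.015) over the 173 tested genes left when 17 listed genes that are 4-fold higher in cord monocytes were taken out. A length trend stays open: length and fold were related across genes in both comparisons (Spearman's rho -0.24 for DKI against WT and 0.38 for CCL17), and with the trend removed the median fell to 0.048 (SE 0.009), with a camera p of 0.000196 and 0.119 with an estimated correlation. Of 10 splits of the 6 libraries, 3 gave a median as large for this list, the real one (0.11) and 2 with replicate 1 of both groups on one side (highest 0.151), while 2 did so for the genes higher in DKI (real 0.043 in size, highest other 0.047), and 10 splits are too few for a share under 0.05.

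Macrophage genes were lower with than without CCL17, although CD4+ T cells had been sorted, which would remove most macrophages. A loss of all non-T cells alike would have lowered B cell markers too, but their median was 0.13 (bootstrap SE 0.026 over genes, not libraries). In the same-number pairs it was 0.34, 0.07 and -0.02, against -0.19, -0.32 and -0.37 for myeloid markers. B cell markers thus fell less than myeloid markers or rose in each pair, but the size of their rise rests on replicate 1. A length trend is not the whole cause, as the myeloid list kept a median of -0.22 (SE 0.033) in the blocked fit with that trend removed. A smaller share of macrophages in the sorted cells may account for it and stays open: 10 genes that only myeloid cells bring were all lower (median -0.32, from -0.496 to -0.114). The variance of their folds was 2.34 times what their standard errors give. Its 95% bounds of 0.548 and 4.04 do not exclude 1 common factor. An effect of CCL17 on macrophages in the culture was not tested and stays open as well.

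The DKI libraries of the CCL17 experiment differed from the other DKI libraries in 3823 genes, and the labels give no biological difference between them. The normalization is not the whole cause, since 4028 genes were called after quantile normalization. Other cells in the sort may account for many of the higher genes, as 52.8% of the 417 genes called at least 4-fold higher were at least 4-fold higher in cord monocytes than in Th17 cells, against 6.39% of all tested genes. For the lower genes, dilution of T cell RNA stays open in part: their median was -0.58, and that of 9 T cell genes was -0.35 (SE 0.115). Naive and memory T cell genes had a median of -1.18 (SE 0.2), which is more than dilution gives in the reported fit. Their library medians were 6.23 and 7.10 in DKI cells and 5.42 to 5.78 without CCL17, so the size of this gap depends on the DKI library kept. A difference between the experiments in culture, sort or sequencing cannot be told apart from the groups.

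All 10 splits of the 6 CCL17 libraries called 0 genes, the real one among them, and 6 called at least as many lists as the real 11 (highest other 24). These 10 splits cannot give a share under 0.1. Splits with replicate 1 of both groups on one side gave 1287 to 1824 genes at an unadjusted p under 0.05, against 411 for the real split, which points to a structure of the samples by replicate 1. Among the splits that part all 3 same-number pairs, the other 3 gave 0 genes each with the replicate block, against 2 for the real split, 7, 1 and 11 lists, and 82, 60 and 167 genes at an unadjusted p under 0.05. Their medians were 0.048, 0.016 and 0.050 for the genes lower in DKI, against 0.11 for the real split, but these splits are too few for a share under 0.05.

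The 10 transcripts of the mitochondrial genome had medians of 9.83, 10.26 and 10.40 in bone marrow monocytes, cord monocytes and APCs. All 10 were higher in DKI than in WT Th17 cells (median log2 fold 0.43, camera p 0.000291, and 0.22 with an estimated correlation) and higher with than without CCL17 (0.16, camera p 1.44e-05, and 0.171 with an estimated correlation), and no single gene passed in either. In DKI without CCL17 against DKI cells their median was -0.80 (camera p 1.84e-05, and 0.157 with an estimated correlation), and 9 of the 10 fell. These p-values were not adjusted with those of the other lists, and the cause was not tested.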
